A study of Homo sapiens with 12 samples.

How the data were processed

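The series holds 12 RNA sequencing libraries of AGS and HGC-27 cells, 3 untreated and 3 treated with betulonic acid for 24 h in each line. Per the labels, total RNA was taken with Trizol, mRNA was selected with oligo-dT beads, and dUTP-stranded libraries with inserts near 300 bases were sequenced as read pairs of 150 bases on an Illumina NovaSeq instrument. The concentration of betulonic acid is not given in the labels, and neither is the use of strand in counting or the release of the annotation. The submitters' processing notes name cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6 and, without versions or roles, DESeq2 and edgeR, with GRCh38 as the genome.

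The authors deposited 1 table with 35218 genes, their coordinates and values for each library, and every one names a gene. Per the file headers the table holds counts and FPKM. The counts, called estimated counts here, were made by the authors from the aligned reads before they were deposited. The FPKM values in the same deposited table were made by the authors from those counts, and in 8561 genes checked 99.7% of the ratios of FPKM to estimated counts, scaled by library total, lie within 1% of their gene's median. Gene lengths are used here only as relative lengths implied by these 2 kinds of values. The counts cluster at multiples of 4, with steps of 4 counts 1.45 times, of 8 counts 1.36 times, of 12 counts 1.28 times and of 16 counts 1.27 times as common as their neighbors, so 1 fragment adds about 4 to a count and the counts overstate the number of fragments. All 24 value columns were matched to samples, and 0 per-sample columns were left unmapped. Gene coordinates are those of the deposited table, and 34915 gene identifiers were matched in the reference name table, which served to find list members under older symbols.

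Library totals were 57 to 78.9 x 1e6 estimated counts, about 14.3 to 19.7 x 1e6 fragments after division by 4. Genes were tested with edgeR 4.0.16 in R 4.3.3 after filterByExpr (min.count 10, min.total.count 15), TMM scaling, dispersion estimation and the quasi-likelihood F test, with Benjamini-Hochberg adjustment and a threshold of 0.05. Each line was fitted alone for its own change, and genes kept in both lines were fitted together for the interaction, which is the difference between the lines' changes. Every gene test compares 3 with 3 libraries. The analysis plan, written before the data were examined, assumed FPKM and limma. It held a switch to edgeR if the table held raw whole-number counts. The deposited counts are whole numbers but estimated, so that condition was met only in part. The switch was taken. The plan, the gene lists, the rule for named genes and most alternatives were also fixed before the data were examined.

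Gene sets were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, for lists with at least 5 tested members, and adjusted by Benjamini-Hochberg over all lists of both lines. With the correlation estimated from the residuals of 3 libraries per group in place of the preset value, 0 lists were called, and the report prints both values. The 35 lists covered DNA replication and G1/S, mitosis and G2/M, p53 targets, apoptosis regulators, ATF4 and the integrated stress response, the unfolded protein response, NRF2 targets, heat shock and proteotoxic stress, cholesterol synthesis, fatty acid synthesis, LXR targets, autophagy and lysosome, ferroptosis regulators, glycolysis and hypoxia, nuclear oxidative phosphorylation genes, mitochondrially encoded mRNAs and cytosolic ribosomal proteins. They also covered MYC targets and ribosome biogenesis, replication-dependent histones, NF-kB and cytokines, the interferon response, epithelial-mesenchymal transition and matrix, epithelial junctions and keratins, gastric and intestinal lineage, YAP and TEAD targets, Wnt and TGF-beta targets, immediate-early and MAPK feedback genes, xenobiotic metabolism, metallothioneins and zinc response, DNA repair, proteasome subunits, cytoskeleton, ion and volume transporters, markers of blood cells, and markers of fibroblasts and endothelium. Of 1026 list symbols 1009 were found. A gene counts as called in a list if its adjusted p over all tested genes passes, and the count adjusted over the list alone is given where it differs. List medians are medians of the edgeR log2 changes, and medians under alternatives are on the log2 CPM scale of camera or on the FPKM scale.

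Named genes were chosen by a rule fixed in advance. In each line it takes the 10 largest rises and the 10 largest falls in log2(FPKM + 1) among called genes with all 3 treated values on 1 side of the untreated ones and a mean of at least 5 FPKM in the higher group. It adds the 3 called members with the smallest adjusted p in each called list, the 5 genes per direction with the largest change shared by both lines, the 5 per direction with the largest difference between lines, and 10 genes fixed by name, among them CDKN1A, MKI67, HMGCS1, DDIT3, HMOX1, BCL2, ABCA1 and MYC. Some genes that the rule or the lists hold are not reported here. MT-RNR1, MT-RNR2, HNF4A and members named because they went against their list, or because their count was 5 or fewer, were chosen after their values were seen. Some genes that the rule names in 1 line are also given in the other. Where a group has a count of 0 in every library, the change is given as a lower bound with 3 fragments per library, taken as 12 counts, in place of 0. Intervals at 95% are computed on fragments, as counts divided by 4 and rounded up. Bounds and intervals cover counting error only and rest on the approximate figure of 4 counts per fragment, which was found after the data were seen. A list's median is also given with genes at their bound where that moves it.

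The log2 changes differ from ratios of the FPKM means because TMM sets the scale. MT-RNR2 in AGS, ATP5F1B and LPCAT3 are examples. The alternatives were no filter, a filter of at least 5 FPKM in 3 libraries, median-ratio scaling, quantile normalization, limma on log2(FPKM + 0.1), plain limma on log2(FPKM + 1), DESeq2 1.42.0, a replicate block, 1 fit of all 12 libraries, a fold threshold of 2, fry, the estimated correlation, and leaving out each library in turn. Chosen after seeing the data were counts divided by 4, tests without mitochondrial genes, protein-coding genes only, removal of the trend on gene length, and limma-trend on log2(FPKM + 1), the test first planned. The FPKM alternatives kept genes with at least 1 FPKM in 3 libraries. The FPKM scale in the report is log2(FPKM + 1), with its own filter and limma in place of edgeR, and quantile normalization also uses limma.

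On negative binomial counts simulated with the real means, dispersions and library sizes, with 1 mean for treated and untreated libraries and known changes added to 67, 67 and 66 genes, the AGS test recovered 2 of 67 genes changed 1.5-fold, 23 of 67 changed 2-fold and 48 of 66 changed 4-fold, and 5.19% of its calls were false. The HGC-27 test recovered 20, 43 and 40 of the same numbers, with 12.7% of calls false, and the interaction 4, 29 and 44, with 2.53% false. None of 35 random lists was called, and a list holding the added changes was called each time. The genes were simulated independently, so this check does not bear on lists whose members move together. Few genes were changed, so it does not test the scaling when most genes change. Sample splits were drawn 10 per line and 100 for results that use both lines, with 100000 resamples for permutation tests and 1000 random divisions of the genes. Other software was Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.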

Results

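RNA sequencing measured the polyadenylated transcripts of AGS and HGC-27, which are human gastric cancer lines, left untreated or exposed to betulonic acid, a pentacyclic triterpenoid named in the series title as a constituent of Celastrus orbiculatus. Each line received the concentration that inhibits its own growth by 50 percent, per the labels, for 24 h. The concentrations themselves are not stated in the labels. There were 3 libraries in each of the 4 groups, 12 in all. Library totals were 66.7, 63.4 and 68.9 x 1e6 estimated counts in untreated AGS, and 77.0, 60.1 and 78.9 x 1e6 in treated AGS. Untreated HGC-27 had 61.8, 57 and 65.9 x 1e6, and treated HGC-27 had 60.7, 76.4 and 67.7 x 1e6. The labels do not state whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between libraries, which may be technical. Errors after ± are standard errors (SE) for log2 changes and standard deviations (SD) for FPKM, with n = 3 libraries per group throughout. Log2 changes come from edgeR with its own library scaling, so they differ in part from the ratio of the FPKM printed beside them.

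The first comparison asked which genes betulonic acid changed in AGS. Of 17198 genes tested, 10311 changed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4941 higher and 5370 lower after treatment. Most tested genes of the integrated stress response, the unfolded protein response and the NRF2 antioxidant response rose, while most of DNA replication, mitosis and DNA repair and all mitochondrially encoded mRNAs fell. Camera called these lists at the preset correlation, and every one of these calls ends with an estimated correlation (adjusted p from 0.120 to 0.372). Of the changed genes, 2842 rose and 3808 fell by at least 2-fold. The share of called genes that were higher was 47.9%, 49.2% with median-ratio scaling, and 51.5% with quantile normalization, which moved the median log2 change of all tested genes by 0.11. With limma on log2(FPKM + 1), which changes test, scaling and filter together, 11005 genes were tested, 2891 rose and 5071 fell, a share of 36.3%. Over the 10983 genes tested both ways the median moved by -0.27.

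Genes that respond to stress kinases acting on translation were among the largest rises in AGS. TRIB3 (ENSG00000101255), an ATF4 and CHOP target on GRCh38 chromosome 20 (362835 to 397559), went from 0.0806 ± 0.0359 to 81.0 ± 34.6 FPKM, a log2 change of 10.26 ± 0.56 (edgeR adjusted p = 4.6e-06). DDIT3 (ENSG00000175197), which encodes the transcription factor CHOP and lies on chromosome 12 (57516588 to 57521737), rose from 5.26 ± 0.460 to 200.2 ± 47.6 FPKM, a log2 change of 5.57 ± 0.24 (edgeR adjusted p = 2.1e-06). PPP1R15A, the stress-induced regulator of the eIF2 alpha phosphatase, rose by 5.17 ± 0.22, and ATF3 by 4.24 ± 0.16. CHAC1, which degrades glutathione, rose by 4.62 ± 0.16, and SLC3A2, a subunit of amino acid transporters, by 4.27 ± 0.15. Of the 35 tested members of the integrated stress response list, 31 rose, with a median log2 change of 2.1, or 1.95 with a gene at its bound, and EPRS1 and CBS fell. Camera gave an adjusted p = 1.9e-12 for this list, and adjusted p = 0.124 with an estimated correlation. Ranges over the camera alternatives include the estimated correlation and leave out fry, which asks whether a list changed at all. The value in brackets after an alternative is a list median on the log2 CPM scale of the list test, or a gene's log2 change. Counts of list members adjusted over the list alone were the same as those over all genes tested, here and below, unless given. DDIT4, an mTORC1 inhibitor induced by stress, belongs to the same list and rose by 5.42 ± 0.20. With 1 added to the FPKM before the logarithm, genes near 0 FPKM in 1 group have smaller changes, here and below. Examples are 6.14 for TRIB3, 7.49 for HSPA6, -1.45 for CLSPN, -1.80 for UTP20, -2.32 for MCM10, -1.98 for FANCI and -2.08 for FANCD2 in AGS, and 3.73 for DHRS2 and -1.13 for ABCA1 in HGC-27.

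Of 27 tested members of the unfolded protein response list, 22 rose in AGS, 23 adjusted over the list alone, and the median was 1.41. HERPUD1, which takes part in degradation of misfolded proteins, rose by 4.06 ± 0.20, XBP1 by 1.98 ± 0.11 and the ubiquitin ligase gene SYVN1 by 2.44 ± 0.15. HSP90B1 and DNAJC3 fell, and 3 members fell when adjusted over the list alone. Camera gave an adjusted p = 3.9e-07, and adjusted p = 0.218 with an estimated correlation, and the median was 0.88 on the FPKM scale. The heat shock list was not called (adjusted p = 0.277), with 13 of 23 members higher and 7 lower and a median of 0.57. It was called without treated library 1 (0.78), with camera adjusted p from 0.0284 to 0.828 over the camera alternatives. HSPA6 (ENSG00000173110), an inducible HSP70 gene on chromosome 1 (161524540 to 161526894), had the largest rise of the named genes in log2(FPKM + 1). It went from 0.158 ± 0.0548 to 242 ± 137 FPKM, a log2 change of 10.88 ± 0.73 (edgeR adjusted p = 9.4e-06). It shares reads with its near copy HSPA7, so its level is uncertain.

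NRF2 targets rose in AGS in 23 of 31 cases, with 0 lower and a median of 2.09 (camera adjusted p = 8.8e-09, and adjusted p = 0.155 with an estimated correlation). HMOX1 (ENSG00000100292), which encodes heme oxygenase 1 and lies on chromosome 22 (35380361 to 35394214), rose from 13.2 ± 0.762 to 285 ± 40.1 FPKM, a log2 change of 4.75 ± 0.15 (edgeR adjusted p = 9.8e-07). SRXN1, which reduces oxidized peroxiredoxins, rose by 5.17 ± 0.15 and OSGIN1 by 4.48 ± 0.12. On the FPKM scale the list's median was 1.40. Ferritin transcripts of FTL and FTH1 made up 0.681% ± 0.0282 of untreated and 6.16% ± 0.685 of treated AGS counts. Part of the ferritin signal is uncertain because pseudogenes share these sequences. Metallothionein and zinc response genes rose in 4 of 6 cases, MT1F, MT1X, MT2A and SLC30A1, while SLC39A10 fell, and the median was 2.94. MT2A, a metal-binding protein gene with near copies, rose from 42.5 ± 1.93 to 2321 ± 504 FPKM, a log2 change of 6.10 ± 0.24, and MT1X rose by 5.73 ± 0.20. Camera gave this list an adjusted p = 0.0312, and adjusted p = 0.216 with an estimated correlation. Its median was 4.18 without treated library 1, 3.67, 3.67 and 3.65 without untreated libraries 1, 2 and 3, and 2.15 on the FPKM scale.

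MKI67 (ENSG00000148773), the proliferation marker Ki-67 on chromosome 10 (128096659 to 128126423), fell from 21 ± 0.753 to 1.01 ± 0.191 FPKM, a log2 change of -4.07 ± 0.16 (edgeR adjusted p = 1.3e-06), or -3.42 with the trend on transcript length removed. In the mitosis list 36 of 40 members fell, 37 adjusted over the list alone, CKS2 rose, and the median was -1.95 (camera adjusted p = 1.9e-12, and adjusted p = 0.128 with an estimated correlation). ECT2, KIF23 and BUB1, which act in cytokinesis and the spindle checkpoint, changed by -3.94 ± 0.13, -3.78 ± 0.14 and -3.41 ± 0.13. In the DNA replication list 36 of 40 members fell, CDC6 rose, and the median was -1.53 (camera adjusted p = 1.8e-10, and adjusted p = 0.155 with an estimated correlation). MCM10 and CLSPN, which act at replication forks, changed by -3.80 ± 0.20 and -3.40 ± 0.19, and the thymidylate synthase gene TYMS by -3.34 ± 0.20. Of 36 DNA repair members, 34 fell and ERCC1 rose, with a median of -2.46 (camera adjusted p = 1.2e-10, and adjusted p = 0.120 with an estimated correlation). The Fanconi anemia genes FANCI and FANCD2 changed by -3.27 ± 0.12 and -3.31 ± 0.15, or -2.41 and -2.71 with the length trend removed. On the log2 CPM scale of the list test, the DNA repair median of -2.48 became -1.04 with the stricter FPKM filter and -1.27 on the FPKM scale.

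All 13 mitochondrially encoded mRNAs fell in AGS, with a median of -2.90 (camera adjusted p = 1.1e-06, and adjusted p = 0.372 with an estimated correlation). MT-ND6 (ENSG00000198695), the complex I subunit gene of the light strand (14149 to 14673 on the mitochondrial chromosome), fell from 3083 ± 212 to 129 ± 34.5 FPKM, a log2 change of -4.25 ± 0.23. MT-CO2 changed by -4.19 ± 0.33, MT-ND5 by -3.43 ± 0.22 and MT-CO1 by -2.78 ± 0.23. These mRNAs together made up 7.17% ± 0.204 of untreated and 0.828% ± 0.242 of treated AGS counts. The mitochondrial rRNA gene MT-RNR1 rose by 1.36 ± 0.20, and MT-RNR2 had a change of 0.01 ± 0.16 that did not pass the test. Of nuclear genes for oxidative phosphorylation, 25 of 43 rose, 26 adjusted over the list alone, while NDUFS1, SDHA, UQCRC2 and ATP5PB fell, and the median was 0.53. NDUFA1 and NDUFB5, complex I subunit genes, rose by 1.97 ± 0.24 and 0.97 ± 0.12. Camera gave an adjusted p = 0.0025, and adjusted p = 0.573 with an estimated correlation. The call also ended with the stricter filter, quantile normalization and the FPKM scale, with medians of 0.31, 0.35 and 0.18 and camera adjusted p from 0.000163 to 0.573 over the camera alternatives.

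Every one of 50 cytosolic ribosomal protein genes rose in AGS, with a median of 1.19 (camera adjusted p = 2.9e-12, and adjusted p = 0.417 with an estimated correlation). RPL3 rose by 1.32 ± 0.13, or 0.79 with quantile normalization, and RPS12 by 1.78 ± 0.19, and both have processed pseudogenes that share reads. With quantile normalization the list's median was 0.72. Genes of ribosome biogenesis and other MYC targets went the other way. There 28 of 36 fell, 29 adjusted over the list alone, while GAR1, RRP12 and ODC1 rose, and the median was -0.84 (camera adjusted p = 3.8e-05, and adjusted p = 0.218 with an estimated correlation). UTP20 and the nucleolin gene NCL changed by -3.81 ± 0.15 and -2.18 ± 0.17, and MYC itself by -0.84 ± 0.13, from 26.9 ± 1.77 to 12.2 ± 2.51 FPKM. Of 31 proteasome subunit genes 15 rose, PSMC6, PSMD1, PSMD12 and PSMD14 fell, and the median was 0.28 (camera adjusted p = 0.0259, and adjusted p = 0.577 with an estimated correlation). On the FPKM scale the proteasome median was -0.04, and the call ended there, with quantile normalization (0.08) and with the stricter filter (0.09), with camera adjusted p from 0.0039 to 0.594 over the camera alternatives.

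FASN (ENSG00000169710), the fatty acid synthase gene on chromosome 17 (82078338 to 82098294), fell from 139 ± 5.93 to 16.8 ± 6.34 FPKM, a log2 change of -2.74 ± 0.23 (edgeR adjusted p = 2.7e-05). ACACA, which makes malonyl-CoA, changed by -3.08 ± 0.29, or -2.45 with the length trend removed. Of 15 fatty acid synthesis genes 10 fell, ACSS2, ELOVL1 and MID1IP1 rose, and the median was -1.20 (camera adjusted p = 0.0457, and adjusted p = 0.517 with an estimated correlation). That call ended without treated library 2 (-1.12) or 3 (-1.11), with the stricter filter (-1.30), on the FPKM scale (-1.22) and with the transcript-length trend removed (-1.20), with camera adjusted p from 0.0192 to 0.517 over the camera alternatives. Of 27 cholesterol synthesis genes 17 fell, PMVK and TM7SF2 rose, and the median was -0.67 (camera adjusted p = 0.0026, and adjusted p = 0.216 with an estimated correlation). HMGCS1 and IDI1 changed by -2.47 ± 0.16 and -1.55 ± 0.11, and INSIG1 by -1.36 ± 0.11. Among 9 LXR targets SMPDL3A and NR1H2 rose and ABCA1 and SREBF1 fell, and the list was not called (median 0.33, mean -0.00, camera adjusted p = 0.654). ABCA1, the cholesterol efflux transporter, was scarce in AGS at 0.198 ± 0.0188 FPKM and changed by -2.87 ± 0.34.

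Other lists called in AGS were the following. Of 36 autophagy and lysosome genes 24 rose, ATP6V1A and ASAH1 fell, and the median was 0.67 (camera adjusted p = 1.1e-05, and adjusted p = 0.142 with an estimated correlation). On the log2 CPM scale of that test the median of 0.65 became 0.32 on the FPKM scale and 0.98 with the length trend removed. SQSTM1, which encodes the autophagy receptor p62 and is also an NRF2 target, rose by 4.37 ± 0.14, WIPI1 by 4.24 ± 0.16 and MAP1LC3B by 2.96 ± 0.16. Immediate-early and MAPK feedback genes rose in 24 of 32 cases, DUSP4, SPRED1, PHLDA1 and AREG fell, and the median was 1.56 (camera adjusted p = 2.6e-07, and adjusted p = 0.124 with an estimated correlation). EGR1, DUSP1 and KLF2 rose by 5.65 ± 0.17, 4.82 ± 0.19 and 4.18 ± 0.11. Interferon response genes fell in 22 of 34 cases, 23 adjusted over the list alone, ISG20, IRF1, IRF7, IRF9 and TAP1 rose, and the median was -1.90 (camera adjusted p = 0.0025, and adjusted p = 0.378 with an estimated correlation). IFI6 changed by -1.74 ± 0.13, and BST2, at 2.38 ± 0.498 FPKM untreated, by -3.76 ± 0.55. The interferon call ended with the stricter filter (-1.37) and on the FPKM scale (-1.13), with camera adjusted p from 0.00075 to 0.378 over the camera alternatives.

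Of 21 replication-dependent histone genes 11 rose in AGS and 0 fell, with a median of 1.35 (camera adjusted p = 0.0263, and adjusted p = 0.627 with an estimated correlation). H2AC6 rose by 2.63 ± 0.28. Most histone mRNAs lack a poly(A) tail, so this method sees only a part of them. RN7SK, which also lacks a tail, was at 21.8, 157 and 115 FPKM in treated AGS libraries 1, 2 and 3, against 28.8, 83.2 and 53.5 FPKM for the histone gene H1-2. Carry-over of RNA without tails was not tested in either line. The histone call ended without treated library 2 (0.79), with fry (adjusted p = 0.0715) and with the length trend removed (0.93), with camera adjusted p from 0.0015 to 0.627 over the camera alternatives, and the median was 0.67 on the FPKM scale. Cytoskeleton genes fell in 16 of 30 cases, TUBA4A, TUBB2A, TUBB2B and ZYX rose, and the median was -0.48 (camera adjusted p = 0.0401, and adjusted p = 0.259 with an estimated correlation). CALD1 and TAGLN, actin-binding protein genes, changed by -2.68 ± 0.16 and -2.01 ± 0.15. This call ended without untreated library 1 (-0.48) or 3 (-0.48) or treated library 1 (-0.56), and with the length trend removed (-0.28), with camera adjusted p from 0.00031 to 0.259 over the camera alternatives, and the median was -0.81 with quantile normalization. Ion and volume transporter genes fell in 13 of 20 cases, SLC6A6 and AKR1B1 were among those that rose, and the median was -0.77 (camera adjusted p = 0.0312, and adjusted p = 0.517 with an estimated correlation). SLC12A2, the NKCC1 cotransporter gene, changed by -3.80 ± 0.14. The transporter call ended without treated library 2 (-0.69), with the stricter filter (-0.48), on the FPKM scale (-0.80) and with the length trend removed (-0.41), with camera adjusted p from 0.0044 to 0.517 over the camera alternatives.

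The remaining lists were not called by camera in AGS. Fry called the apoptosis, ferroptosis, epithelial junction, gastric lineage, YAP, Wnt and TGF-beta, xenobiotic and fibroblast lists among them, with adjusted p from 3.1e-05 to 0.0036. For p53 targets 8 of 29 rose and 12 fell (median -0.07, adjusted p = 0.817). CDKN1A, the p21 cell cycle inhibitor gene, rose from 130 ± 4.51 to 228 ± 27.9 FPKM, a log2 change of 1.13 ± 0.11, which was 0.75 with quantile normalization. GDF15 and GADD45A rose by 2.81 ± 0.23 and 2.92 ± 0.13. Of 29 apoptosis regulators 13 rose and 9 fell, 10 adjusted over the list alone (median 0.21, adjusted p = 0.293). BCL2 was near the detection limit at 0.0988 ± 0.0152 FPKM and had a change of -0.89 ± 0.35 that did not pass the test, except without treated library 3 (-1.10). Ferroptosis regulators had 8 of 21 higher, 9 adjusted over the list alone, and 7 lower (median 0.20, adjusted p = 0.407). Glycolysis and hypoxia genes had 11 of 34 higher and 11 lower (median 0.15, adjusted p = 0.524), and the test direction turned with the stricter filter (-0.31) and quantile normalization (-0.10). The NF-kB list had 9 of 23 higher and 8 lower, 9 adjusted over the list alone (median -0.21, mean 0.09, test direction down, adjusted p = 0.953), and that direction turned without treated library 2 (-0.09) and with the stricter filter (-0.06). The matrix and mesenchymal list had 9 of 26 higher and 10 lower (mean -0.07, median and test direction above 0, adjusted p = 0.969), and the test direction turned without untreated library 2 (-0.23) or 3 (-0.16) or treated library 2 (-0.24) or 3 (-0.51). Epithelial junction and keratin genes had 8 of 27 higher and 15 lower, 16 adjusted over the list alone (median -0.43, adjusted p = 0.293), and the list was called with quantile normalization (-0.85). Among 20 gastric and intestinal lineage genes GATA4, FOXA1, FOXA2, FOXA3 and AGR2 rose and 11 fell (median -0.66, adjusted p = 0.134), a list called without untreated library 2 (-1.27). YAP targets had 6 of 18 higher and 11 lower (median -0.75, adjusted p = 0.133). Wnt and TGF-beta targets had 6 of 25 higher and 13 lower (median -1.0, camera adjusted p = 0.0518), and were called with quantile normalization (-0.78) and without untreated library 2 (-0.996), untreated library 3 (-1.06) or treated library 1 (-1.02), with camera adjusted p from 0.0272 to 0.510 over the camera alternatives. Xenobiotic metabolism genes had 6 of 17 higher, 8 adjusted over the list alone, and UGT1A6, ABCG2 and SULT2B1 fell (median 0.46, adjusted p = 0.190). Of the marker lists of cells that a pure culture should lack, the blood list had CD68 higher and LYZ lower among 5 (median 1.23, adjusted p = 0.516). The fibroblast and endothelium list had PDGFRA, ACTA2 and DES lower among 5 (median -1.88, adjusted p = 0.0607), and was called without treated library 1 (-2.21).

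Among single genes outside these lists, SPRR2D, a cornified envelope gene, rose in AGS by 6.79 ± 0.20, S100P by 5.82 ± 0.23 from 7.97 ± 1.74 to 361 ± 60.7 FPKM, and the uridine phosphorylase gene UPP1 by 5.12 ± 0.14. ALPP, the placental alkaline phosphatase gene, fell from 106 ± 6.89 to 1.11 ± 0.380 FPKM, a log2 change of -6.25 ± 0.23, and shares reads with ALPG. The Wnt antagonist gene DKK1 changed by -4.43 ± 0.19 and ENC1 by -4.11 ± 0.21. Several of the largest falls were mitochondrial tRNA genes such as MT-TY (-4.29 ± 0.12), which are shorter than the sequenced inserts and lie beside the mRNAs. RN7SK, an RNA without a poly(A) tail, rose by 6.59 ± 0.82. Changes in AGS ran against transcript length. The shortest 10% of protein-coding genes had a median log2 change of 0.60, with 620 higher and 186 lower, and the longest 10% had a median of -0.91, with 161 higher and 768 lower. Spearman's rho of change with relative transcript length across 12791 genes, which are not independent replicates, was -0.31, and -0.26, -0.35 and -0.28 in the 3 treated libraries taken singly. The treated AGS libraries also differed more among themselves than other replicates. The chi-square per degree of freedom between pairs was 40.1 to 86.8 in treated AGS against 4.33 to 12.3 in the other groups. With the length trend removed, the median of the DNA repair list was -1.95, of the mitosis list -2.04 and of the ribosomal protein list 1.12.

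**Figure D1:**
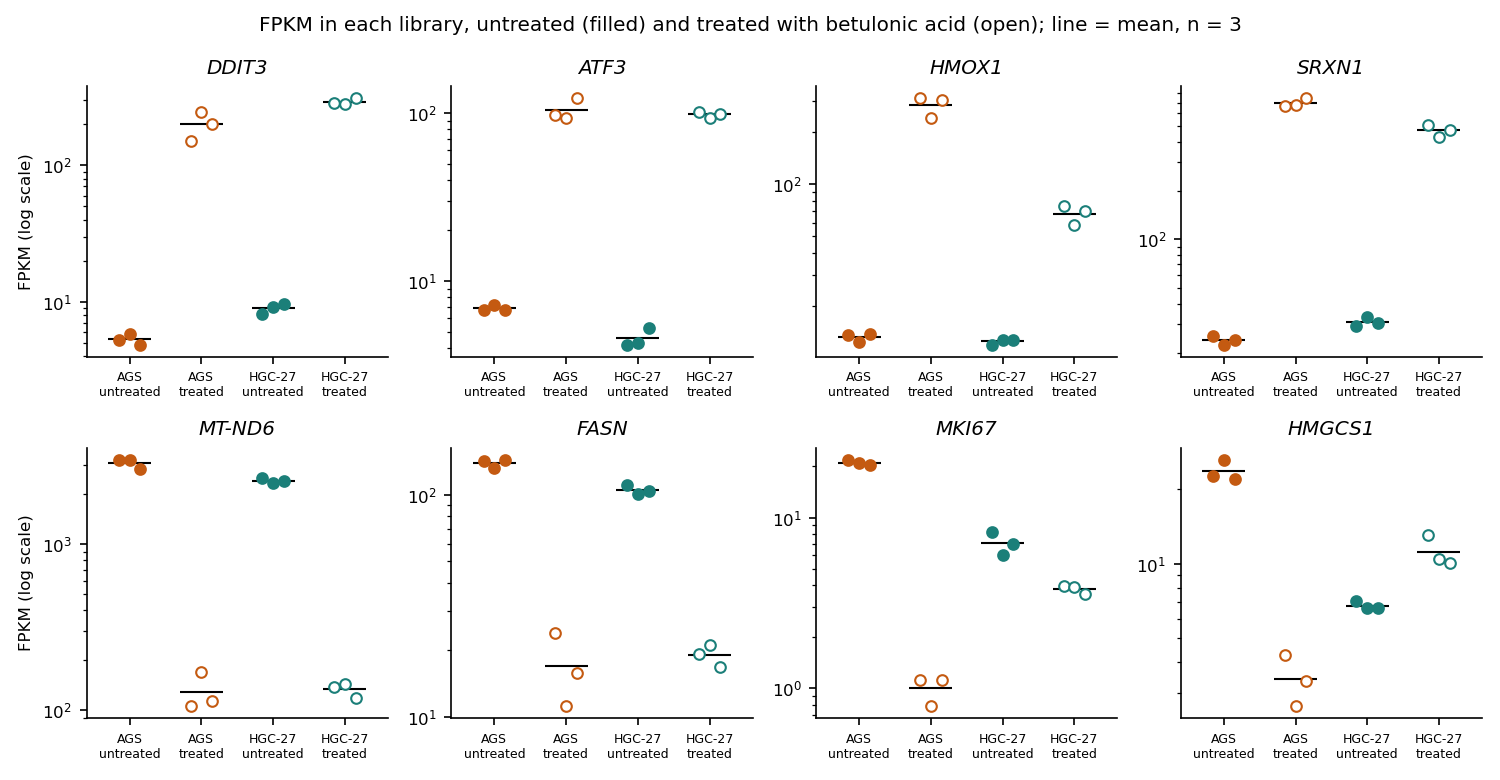
FPKM on a log axis of 8 named genes in each library, with untreated libraries filled, treated libraries open and a line at the mean of n = 3. DDIT3, ATF3, HMOX1 and SRXN1 lie higher and MT-ND6, FASN and MKI67 lower after treatment in both lines, while HMGCS1 went from 23.7 to 3.43 FPKM in AGS and from 6.76 to 11.2 FPKM in HGC-27.

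The second comparison asked the same question in HGC-27. Of 18746 genes tested, 10922 changed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 5693 higher and 5229 lower. The majority turned in 1 fit of all 12 libraries, with 4473 higher and 4926 lower, and limma on log2(FPKM + 1) gave 5306 higher and 3435 lower. Most tested genes of the unfolded protein response, the integrated stress response and the NRF2 list rose, and most of DNA replication, cytoskeleton and extracellular matrix and all mitochondrially encoded mRNAs fell. Camera called these lists at the preset correlation, and every one of these calls ends with an estimated correlation (adjusted p from 0.120 to 0.238). Of the changed genes, 2671 rose and 2552 fell by at least 2-fold. With limma on log2(FPKM + 1) the median log2 change moved by 0.15 over the 11073 genes tested both ways.

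Each of the 27 tested unfolded protein response genes rose in HGC-27, with a median of 1.62 (camera adjusted p = 1.1e-14, and adjusted p = 0.216 with an estimated correlation). DNAJB9, an endoplasmic reticulum cochaperone, rose from 0.984 ± 0.0779 to 36.5 ± 7.42 FPKM, a log2 change of 5.00 ± 0.16 (edgeR adjusted p = 4.1e-09). HERPUD1 rose by 3.87 ± 0.09, XBP1 by 2.54 ± 0.06 and SYVN1 by 2.03 ± 0.08. Of 36 integrated stress response genes 33 rose and 0 fell, with a median of 1.04 (camera adjusted p = 9.3e-13, and adjusted p = 0.216 with an estimated correlation). DDIT3 rose from 8.92 ± 0.774 to 294 ± 14.8 FPKM, a log2 change of 4.84 ± 0.09 (edgeR adjusted p = 5.3e-10). PPP1R15A rose by 4.57 ± 0.09, ATF3 by 4.22 ± 0.10, TRIB3 by 3.33 ± 0.08, SLC3A2 by 2.82 ± 0.08 and CHAC1 by 1.47 ± 0.12. DDIT4 had a change of -0.04 ± 0.11 that did not pass the test. Its sign turned with quantile normalization (0.16), on the FPKM scale (0.16), without untreated library 3 (0.05) and without treated library 1 (0.03). Of 32 NRF2 targets 24 rose, TALDO1, TKT, CBR1 and ALDH3A1 were among those that fell, and the median was 1.24 (camera adjusted p = 1.7e-05, and adjusted p = 0.152 with an estimated correlation). TALDO1 and TKT encode pentose phosphate pathway enzymes. OSGIN1 (ENSG00000140961), on chromosome 16 (83931311 to 83966332), rose from 1.89 ± 0.159 to 73.8 ± 3.58 FPKM, a log2 change of 5.08 ± 0.09 (edgeR adjusted p = 5.3e-10). SRXN1 rose by 3.73 ± 0.08, TRIM16 by 2.45 ± 0.08 and HMOX1 by 2.25 ± 0.09, from 12.4 ± 0.450 to 67.8 ± 8.55 FPKM. FTL and FTH1 together made up 0.314% ± 0.00615 of untreated and 0.750% ± 0.0289 of treated HGC-27 counts. In the heat shock list DNAJB1, DNAJA1, BAG3, DNAJB4 and HSPB8 rose and 11 of 23 fell (median -0.16, adjusted p = 0.268), and HSPA6 had a change of 0.32 ± 0.27 that did not pass the test.

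The 13 mitochondrially encoded mRNAs also fell in HGC-27, with a median of -2.66 (camera adjusted p = 1.2e-10, and adjusted p = 0.238 with an estimated correlation). MT-ND6 fell from 2408 ± 82.6 to 133 ± 13.9 FPKM, a log2 change of -4.37 ± 0.09, and MT-ND5, MT-CO2 and MT-CO1 changed by -3.56 ± 0.09, -3.43 ± 0.13 and -2.95 ± 0.08. Their share of counts was 6.59% ± 0.451 untreated and 1.15% ± 0.129 treated. MT-RNR1 and MT-RNR2 rose by 1.05 ± 0.09 and 0.32 ± 0.09. Nuclear oxidative phosphorylation genes fell in 22 of 43 cases, 23 adjusted over the list alone, and rose in 8, 9 adjusted over the list alone, with a median of -0.19 (camera adjusted p = 0.0118, and adjusted p = 0.575 with an estimated correlation). SDHA changed by -1.08 ± 0.06 and ATP5F1B by -0.92 ± 0.06. The median of this list turned to 0.04 with quantile normalization and 0.01 on the FPKM scale, and its call ended there and with the stricter filter (-0.11), with camera adjusted p from 0.0020 to 0.684 over the camera alternatives.

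**Figure D2:**
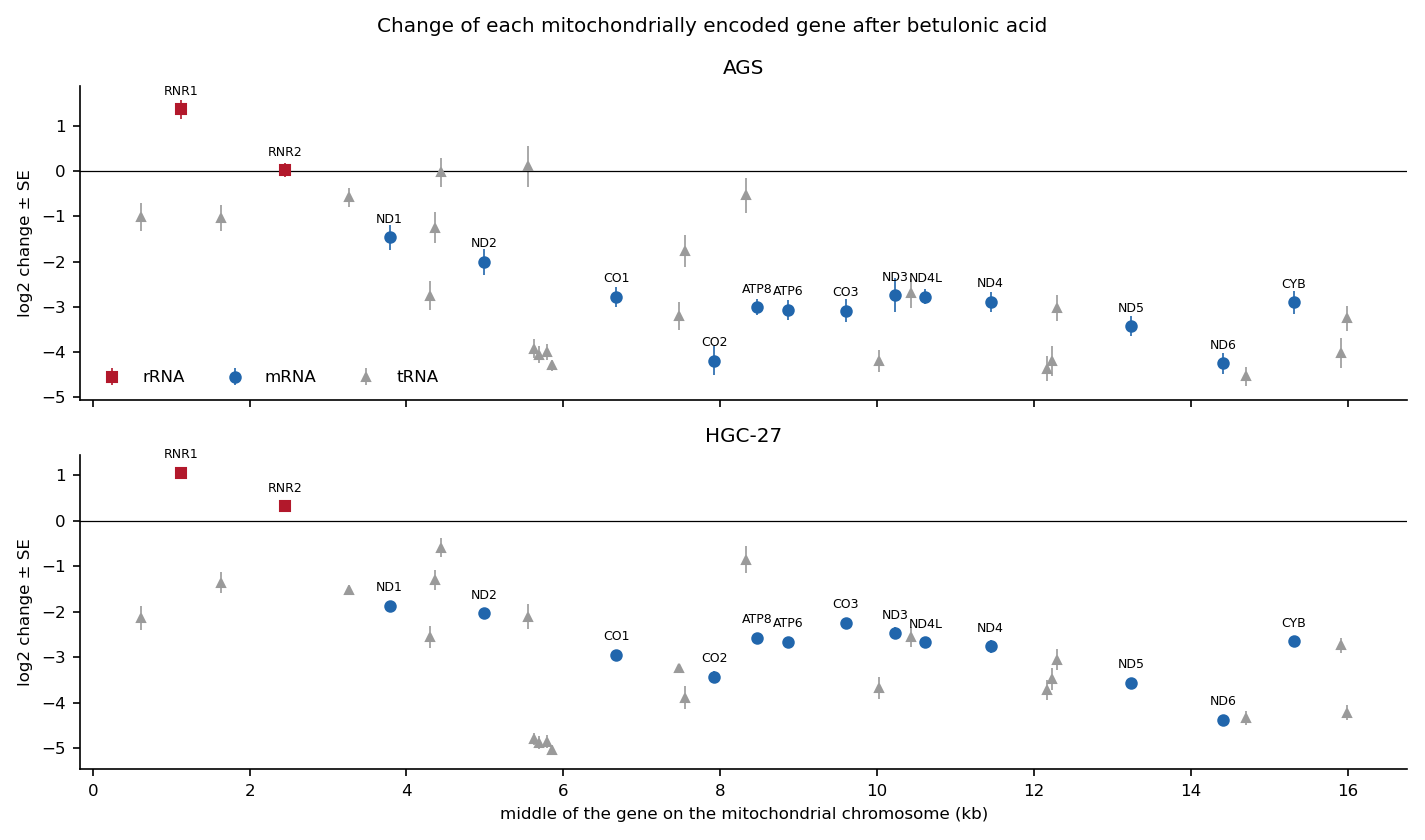
Log2 change with SE of each tested mitochondrially encoded gene against the position of its middle in kilobases, AGS above and HGC-27 below. The mRNAs lie below 0 in both lines, with MT-ND6 at -4.25 in AGS and -4.37 in HGC-27, while MT-RNR1 lies at 1.36 and 1.05.

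DNA replication genes fell in HGC-27 in 37 of 40 cases, CDC6 rose, and the median was -1.44 (camera adjusted p = 3.7e-13, and adjusted p = 0.120 with an estimated correlation). On the FPKM scale the list's median was -0.89. The replicative helicase gene MCM2 changed by -2.53 ± 0.06, TYMS by -2.34 ± 0.10, MCM10 by -1.56 ± 0.12 and CLSPN by -1.47 ± 0.16. Of 36 DNA repair genes 23 fell and 6 rose, 7 adjusted over the list alone, with a median of -0.53 (camera adjusted p = 0.0042, and adjusted p = 0.230 with an estimated correlation). PARP1, which senses DNA breaks, changed by -1.14 ± 0.07, FANCI by -1.13 ± 0.09 and FANCD2 by -0.96 ± 0.12. The repair call ended with the stricter filter (-0.32), with camera adjusted p from 0.0020 to 0.230 over the camera alternatives. In the mitosis list 11 of 40 genes rose and 18 fell, and the list was not called (median -0.13, adjusted p = 0.190), with a median of 0.15 under the stricter filter. MKI67 changed by -1.08 ± 0.10, from 7.07 ± 1.08 to 3.83 ± 0.211 FPKM, ECT2 by -0.82 ± 0.17 and KIF23 by -1.26 ± 0.15. BUB1 had a change of -0.23 ± 0.11 that did not pass the test. The topoisomerase gene TOP2A rose by 0.37 ± 0.12, a call that ended without untreated library 2 (0.31) or 3 (0.33) or treated library 2 (0.20).

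Of 36 MYC target and ribosome biogenesis genes 27 fell in HGC-27, GAR1, RRP12, WDR12, GNL3 and ODC1 rose, and the median was -0.58 (camera adjusted p = 5.5e-06, and adjusted p = 0.120 with an estimated correlation). NCL changed by -1.36 ± 0.06 and UTP20 by -0.53 ± 0.15. MYC fell by 0.29 ± 0.07, from 53.9 ± 2.99 to 50.7 ± 3.19 FPKM, a call that ended on the FPKM scale (-0.09) and with quantile normalization (0.02). Of 50 ribosomal protein genes 27 rose and 9 fell, with a median of 0.25 (camera adjusted p = 0.0480, and adjusted p = 0.728 with an estimated correlation). RPS12 rose by 0.87 ± 0.08, and RPL3 had a change of -0.02 ± 0.07 that did not pass the test. The ribosomal call ended without untreated library 1 (0.17) or 3 (0.23), without treated library 2 (0.18) or 3 (0.22), with median-ratio scaling (0.22), without mitochondrial genes (0.24), with fry (adjusted p = 0.0552) and with the length trend removed (0.21), with camera adjusted p from 1.6e-06 to 0.728 over the camera alternatives. The list's median was 0.43 with quantile normalization. Proteasome genes had 13 of 31 higher and 9 lower (median 0.00, adjusted p = 0.654), and were called with quantile normalization (0.29).

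Fatty acid synthesis genes fell in HGC-27 in 13 of 18 cases, ME1, GPAM and MID1IP1 rose, and the median was -0.59 (camera adjusted p = 0.0015, and adjusted p = 0.155 with an estimated correlation). The list's median was -0.33 on the FPKM scale and -0.93 with the stricter filter. FASN changed by -2.66 ± 0.09, from 105 ± 4.83 to 19.0 ± 2.13 FPKM, and ACACA by -1.31 ± 0.08. The gene for the lipogenic transcription factor SREBP1, SREBF1, changed by -2.27 ± 0.08. Of 9 LXR targets 6 fell and NR1H2 rose, with a median of -0.99 (camera adjusted p = 0.0056, and adjusted p = 0.170 with an estimated correlation). This call ended with the stricter filter (-0.91), with camera adjusted p from 0.0029 to 0.170 over the camera alternatives. LPCAT3, a phospholipid acyltransferase gene, changed by -2.28 ± 0.07 and ABCA1 by -2.81 ± 0.16. Cholesterol synthesis genes were not called as a list, with 8 of 27 higher and 13 lower (median -0.16, adjusted p = 0.173). HMGCS1 and IDI1 rose by 0.52 ± 0.09 and 0.78 ± 0.10, while INSIG1 changed by -0.33 ± 0.08.

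Matrix and mesenchymal genes fell in HGC-27 in 21 of 30 cases, SNAI2 and LOX were among those that rose, and the median was -0.51 (camera adjusted p = 3.7e-05, and adjusted p = 0.155 with an estimated correlation). With the stricter filter the median was -1.09. The fibrillar collagen gene COL1A1 (ENSG00000108821), on chromosome 17 (50184101 to 50201632), fell from 192 ± 11.3 to 17.6 ± 1.89 FPKM, a log2 change of -3.64 ± 0.10 (edgeR adjusted p = 2.1e-09). COL3A1 changed by -2.89 ± 0.07. Wnt and TGF-beta targets fell in 17 of 24 cases, SKIL, ID2, BAMBI, TGIF1 and KLF10 rose, and the median was -0.69 (camera adjusted p = 0.00057, and adjusted p = 0.216 with an estimated correlation). TGFB1 changed by -2.36 ± 0.12. Cytoskeleton genes fell in 26 of 31 cases, 27 adjusted over the list alone, TUBB3 and TPM4 rose, and the median was -1.05 (camera adjusted p = 2.6e-09, and adjusted p = 0.120 with an estimated correlation). The filamin gene FLNA changed by -1.50 ± 0.06, TAGLN by -1.48 ± 0.10 and CALD1 by -0.80 ± 0.17. The list of fibroblast and endothelium markers, most of which HGC-27 itself expresses, fell in 7 of 10 cases, 8 adjusted over the list alone, and VWF rose (median -1.23, camera adjusted p = 0.0051, and adjusted p = 0.20 with an estimated correlation). CD248, which encodes endosialin, fell from 122 ± 6.04 to 5.90 ± 1.51 FPKM, a log2 change of -4.56 ± 0.16, and the intermediate filament gene NES changed by -4.07 ± 0.09.

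Immediate-early and MAPK feedback genes rose in HGC-27 in 27 of 32 cases, KLF2 and DUSP2 fell, and the median was 1.36, or 1.34 with a gene at its bound (camera adjusted p = 3.1e-06, and adjusted p = 0.120 with an estimated correlation). JUN rose from 2.79 ± 0.163 to 88.7 ± 12.0 FPKM, a log2 change of 4.79 ± 0.11, EGR1 by 1.70 ± 0.20 and DUSP1 by 1.38 ± 0.10, and KLF2 changed by -0.63 ± 0.11. Of 29 p53 targets 16 rose and 6 fell, with a median of 0.39 (camera adjusted p = 0.0457, and adjusted p = 0.216 with an estimated correlation). GDF15 rose by 4.67 ± 0.14, GADD45A by 3.85 ± 0.10 and CDKN1A by 0.45 ± 0.06, from 26.6 ± 0.735 to 41.5 ± 1.11 FPKM. The p53 call ended without treated library 1 (0.39) or 2 (0.37), with the stricter filter (0.70), on the FPKM scale (0.61) and with the length trend removed (0.40), with camera adjusted p from 0.0379 to 0.216 over the camera alternatives. Autophagy and lysosome genes rose in 22 of 37 cases and fell in 8, with a median of 0.37 (camera adjusted p = 0.0071, and adjusted p = 0.252 with an estimated correlation), and the median was 0.62 with the stricter filter. WIPI1 rose by 3.79 ± 0.10, MAP1LC3B by 1.67 ± 0.06 and SQSTM1 by 1.27 ± 0.06. Among 5 metallothionein and zinc response genes MT1X, MT2A, SLC30A1 and MTF1 rose, with a median of 0.97 (camera adjusted p = 0.0140, and adjusted p = 0.216 with an estimated correlation). The zinc exporter gene SLC30A1 rose by 3.61 ± 0.08, MT1X by 2.35 ± 0.10 and MT2A by 0.75 ± 0.08. Histone genes rose in 15 of 26 cases and 0 fell, with a median of 1.47, or 1.42 with a gene at its bound (camera adjusted p = 0.0015, and adjusted p = 0.216 with an estimated correlation), and the median was 2.35 with the stricter filter. H2AC6 rose by 3.84 ± 0.12. In treated HGC-27 libraries 1, 2 and 3 RN7SK was at 85.1, 127 and 71.4 FPKM and H1-2 at 110, 116 and 114 FPKM, another order than that of RN7SK, and carry-over of RNA without tails applies here too as an untested limit. Interferon response genes fell in 13 of 33 cases, ISG20, OASL and IRF1 rose, and the median was -0.37 (camera adjusted p = 0.0480, and adjusted p = 0.378 with an estimated correlation). BST2 and IFI6 changed by -1.94 ± 0.13 and -1.56 ± 0.15. The interferon call ended without untreated library 1 (-0.35) or treated library 3 (-0.32), on the FPKM scale (-0.36) and with the length trend removed (-0.42), with camera adjusted p from 0.0303 to 0.378 over the camera alternatives, and the median was -0.85 with the stricter filter.

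Fry called 10 of the lists that camera did not call in HGC-27, with adjusted p from 1.7e-05 to 0.0120, for mitosis, apoptosis, heat shock, cholesterol synthesis, glycolysis, NF-kB, epithelial junctions, gastric lineage, YAP targets and, in the other direction, xenobiotic metabolism. Lists not called by camera in HGC-27 included apoptosis regulators, with 15 of 30 higher and 6 lower, 7 adjusted over the list alone (median 0.40, or 0.36 with a gene at its bound, adjusted p = 0.120). BCL2 had a change of -0.48 ± 0.19 that did not pass the test (edgeR adjusted p = 0.0531) but passed it without untreated library 3 (-0.60) or treated library 1 (-0.64), with median-ratio scaling (-0.51), with DESeq2 (-0.51) and with quantile normalization (-0.56). Ferroptosis regulators had 10 of 20 higher and 7 lower, 8 adjusted over the list alone (median 0.32, adjusted p = 0.517). Glycolysis and hypoxia genes had 14 of 35 higher and 19 lower (median -0.52, adjusted p = 0.107). In the NF-kB list 10 of 20 rose and CCL2, LIF and TNFAIP2 fell, 4 members adjusted over the list alone (median 0.64, or 0.45 with a gene at its bound, adjusted p = 0.147). In the epithelial junction list OCLN, CLDN1, KRT7 and ESRP1 rose and 9 of 19 fell (median -0.74, adjusted p = 0.162). Of 9 gastric lineage genes GATA4, HNF4A and LGALS4 rose and FOXA2 and HNF4G fell (median 0.155, adjusted p = 0.654). HNF4A had a count of 0 in each untreated library and 434 to 498 in the treated ones, at least 31.0-fold higher against a floor of 3 fragments, or 12 counts, per library. YAP targets had 9 of 23 higher and 12 lower (median -0.40, mean 0.01, test direction down, adjusted p = 0.504). In the xenobiotic list 7 of 18 rose and ALDH3A1, SULT1A1, SULT2B1, GSTP1 and GSTO1 fell (median -0.07, mean 0.41, test direction down, adjusted p = 0.994), and that direction turned without treated library 1 (-0.10) and with quantile normalization (-0.18). Transporter genes had 7 of 20 higher, and ATP2B4, SLC4A7, SLC4A2 and KCNN4 were among those that fell, 7 members adjusted over the list alone (median -0.05, adjusted p = 0.856), and the test direction turned without treated library 2 (-0.00), with the stricter filter (0.04), with quantile normalization (-0.01) and on the FPKM scale (0.25). Of 7 blood cell markers ITGAM rose, and HBA1 and HBA2 were among those that fell (median -1.18, mean 0.50, test direction down, adjusted p = 0.471). DHRS2, a short-chain dehydrogenase gene, rose by 6.14 ± 0.16 and RN7SK by 4.64 ± 0.54. SPRR2D had a count of 0 in the untreated libraries and was at least 24.8-fold higher after treatment against the same floor. Spearman's rho of change with transcript length across 13825 genes was -0.02 in HGC-27.

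**Figure D3:**
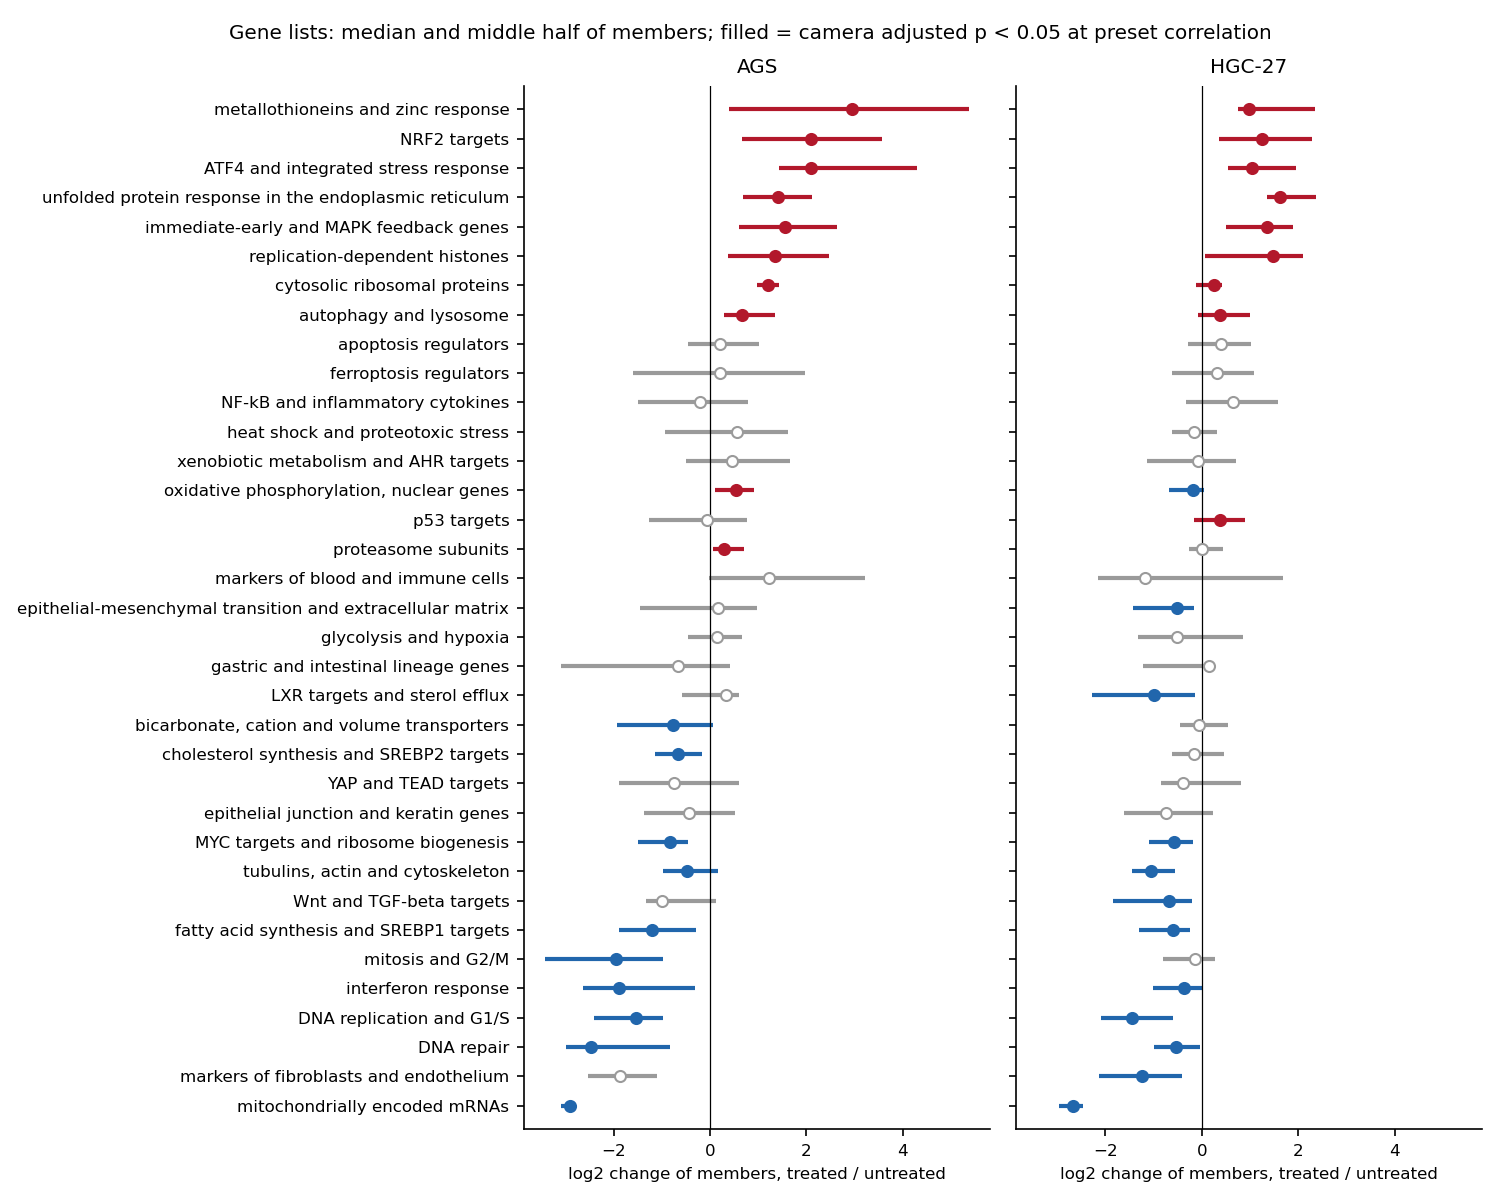
Median (points) and middle 50 percent (lines) of the log2 changes of the members of each gene list, AGS left and HGC-27 right, with filled points for lists called by camera at the preset correlation, red for higher and blue for lower. The mitochondrially encoded mRNAs have medians of -2.90 and -2.66, the unfolded protein response 1.41 and 1.62, and the mitosis list -1.95 and -0.13, and the HGC-27 oxidative phosphorylation median of -0.19 turns above 0 under other scalings.

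The comparison across lines first asked which genes changed the same way in both. Of 15282 genes tested in both lines, 6192 were called in both, and 4420 of these (71.4%) had the same direction. There were 2539 genes higher in both, against 1519 expected from independent lists (odds ratio 4.01, Fisher's exact test, two-sided, p = 1.0e-309), and 1881 lower in both, against 1346 expected (odds ratio 2.16, Fisher's exact test, two-sided, p = 1.5e-92). Genes are not independent replicates, so these p-values describe the overlap of lists. The log2 changes of both lines correlated across genes with a Pearson r of 0.38 and a Spearman rho of 0.36. DDIT3, PPP1R15A, SRXN1 and ATF3 were among the genes with the largest rise shared by both lines, with changes of at least 3.73 in each line, and ATF3 differed by 0.09 ± 0.17 between lines (edgeR adjusted p = 0.682), or by -0.42 with limma on log2(FPKM + 1), which passed the test. Among the largest shared falls MT-ND6 changed by -4.25 ± 0.23 in AGS and -4.37 ± 0.09 in HGC-27, and MT-TY by -4.29 ± 0.12 and -5.03 ± 0.11. FASN fell in both, with a difference of -0.02 ± 0.25 that did not pass the test (edgeR adjusted p = 0.961) but was -0.72 and passed with quantile normalization. Opposite changes were called for 1772 genes, 831 higher in AGS and lower in HGC-27 and 941 the reverse. HMGCS1, IDI1, KLF2, COL1A1, TGFB1 and SLC12A2 were among them.

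**Figure D4:**
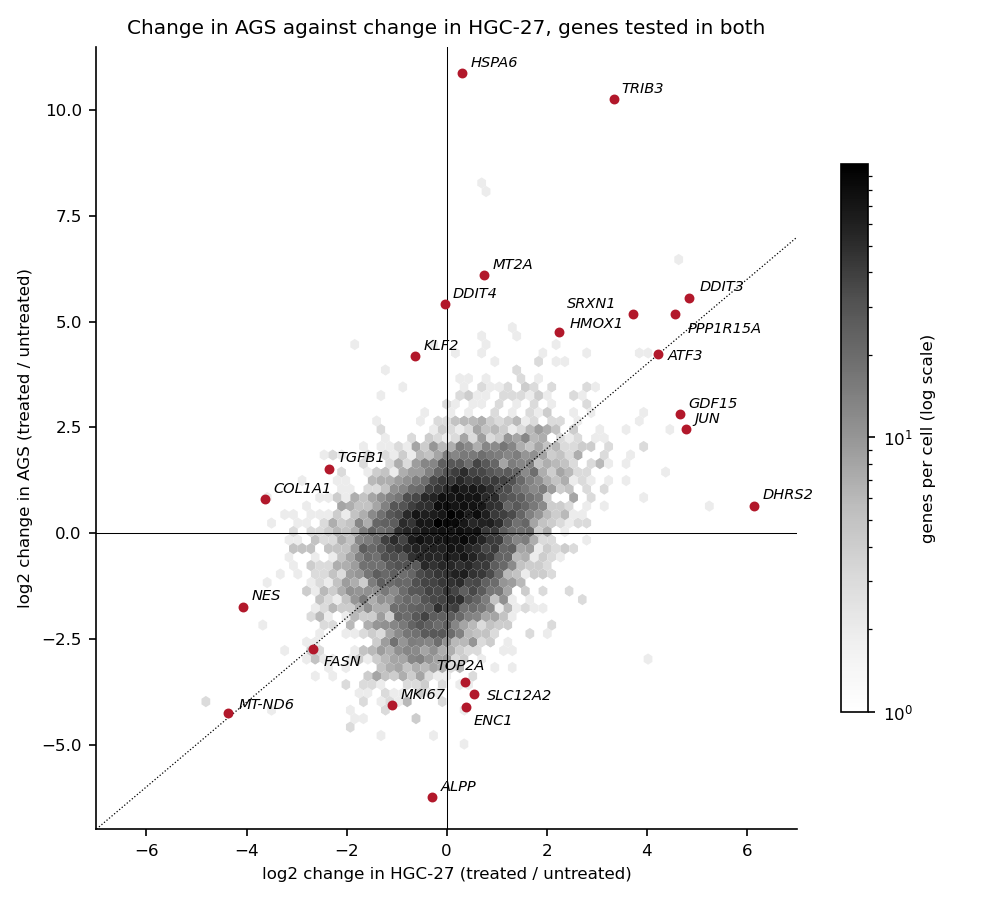
Log2 change in AGS against log2 change in HGC-27 for the 15282 genes tested in both, with darker cells holding more genes, red points for named genes and a dotted line of equal change. DDIT3 lies at 5.57 in AGS and 4.84 in HGC-27, near the dotted line, and HSPA6 at 10.88 and 0.32, far from it.

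The last comparison tested whether the change itself differed between lines, by the interaction term of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. It differed for 8971 of 15282 genes, with the change in AGS above that in HGC-27 for 4405 and below it for 4566. With limma on log2(FPKM + 1), which changes test, scaling and filter together, 9125 genes were tested, 1768 were above and 4298 below. The share above was 29.1%, against 49.1% in the count model, and the median difference moved by -0.53 over the 9109 genes tested both ways. The heat shock gene HSPA6 had the largest difference, 10.62 ± 0.75 (edgeR adjusted p = 2.9e-07). DDIT4 differed by 5.52 ± 0.23, MT2A by 5.41 ± 0.24 and UPP1 by 5.09 ± 0.22, each above in AGS. ALPP differed by -5.96 ± 0.86, or -4.75 without treated HGC-27 library 2 and -5.21 with quantile normalization. It was at 0.136 FPKM or less in every HGC-27 library, so this difference sets the fall in AGS against values near 0 there. DHRS2 differed by -5.42 ± 0.48, ENC1 by -4.42 ± 0.23 and TOP2A by -3.84 ± 0.20, each below in AGS. In HGC-27 ENC1 rose by 0.38 ± 0.15, a call that ended without any 1 of the 6 HGC-27 libraries, where its change was 0.27 to 0.42, and with median-ratio scaling (0.36), DESeq2 (0.36) and quantile normalization (0.29).

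Of 34 lists tested between lines, 11 differed by camera at the preset correlation, and 0 with an estimated correlation, where the smallest adjusted p was 0.115. These tests used TMM scaling, with and without the length trend, and no other scaling. On the FPKM scale the median difference over the genes tested both ways moved by -0.53, a size like that of the smallest list differences here. Larger list differences may depend on scaling too, as single ribosomal and oxidative phosphorylation genes below show. With the length trend removed, an alternative chosen after the data were seen, the mitosis and DNA repair lists passed with an estimated correlation (adjusted p = 0.0397 and 0.0323). The mitosis list fell further in AGS, with a median difference of -1.82 (adjusted p = 1.1e-12, and adjusted p = 0.115 with an estimated correlation), as did the DNA repair list (-1.72, adjusted p = 1.2e-06, and adjusted p = 0.115 with an estimated correlation). MKI67 differed by -2.92 ± 0.19 and BUB1 by -3.11 ± 0.17. The integrated stress response (1.21, adjusted p = 1.6e-07), NRF2 targets (0.93, adjusted p = 0.00027) and autophagy genes (0.55, adjusted p = 0.0252) rose further in AGS. With an estimated correlation adjusted p was 0.164, 0.239 and 0.239. TRIB3 differed by 6.98 ± 0.50 (2.64 on the FPKM scale), HMOX1 by 2.57 ± 0.16 and SQSTM1 by 3.16 ± 0.12. In HGC-27 TRIB3 went from 29.8 to 345 FPKM, above treated AGS (81.0). The unfolded protein response rose less in AGS (-0.50, adjusted p = 0.0476, and adjusted p = 0.590 with an estimated correlation), a call that ended with the length trend removed (adjusted p = 0.102). DNAJB9 and XBP1 differed by -1.02 ± 0.30 and -0.50 ± 0.12. Ribosomal protein genes (1.20, adjusted p = 3.5e-10, and adjusted p = 0.489 with an estimated correlation) and nuclear oxidative phosphorylation genes (0.96, adjusted p = 1.2e-06, and adjusted p = 0.443 with an estimated correlation) were higher in AGS relative to HGC-27. So were LXR targets (1.02, adjusted p = 0.0218, and adjusted p = 0.164 with an estimated correlation), with LPCAT3 at 2.67 ± 0.15. Glycolysis genes (0.53, adjusted p = 0.0218, and adjusted p = 0.287 with an estimated correlation) and cytoskeleton genes (0.53, adjusted p = 0.0252, and adjusted p = 0.311 with an estimated correlation) completed the 11. The DNA replication and mitochondrial mRNA lists were not called as different, with median differences of -0.10 (adjusted p = 0.425) and -0.06 (adjusted p = 0.727). With the length trend removed the mitochondrial mRNA list was called as lower in AGS (-0.58, camera adjusted p = 0.0150, and adjusted p = 0.641 with an estimated correlation).

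**Figure D5:**
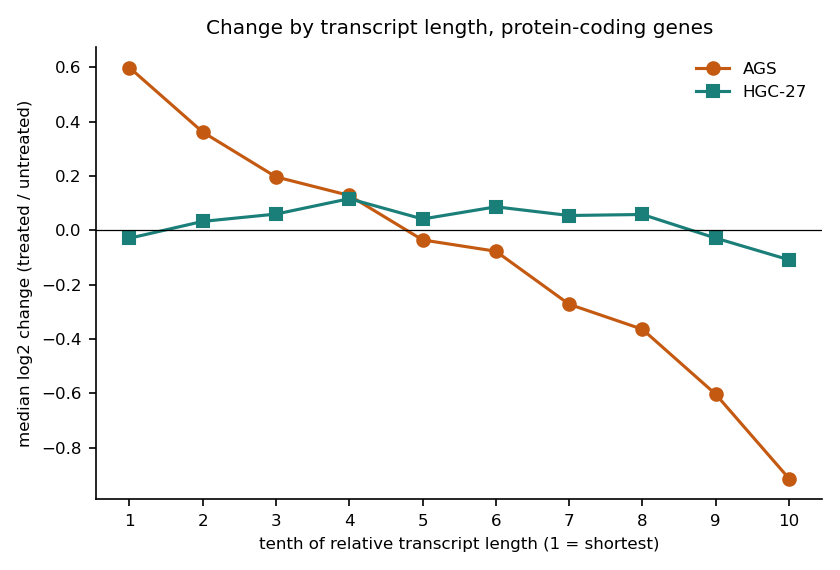
Median log2 change of protein-coding genes in 10 bins of relative transcript length, from the shortest (1) to the longest (10), for AGS (circles) and HGC-27 (squares). The AGS medians run from 0.60 in the shortest bin to -0.91 in the longest, while the HGC-27 medians lie between -0.11 and 0.12.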

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

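The tests on transcript span, on mitochondrial genes and on the mitosis list were chosen only after those results were seen, except the removal of treated AGS library 2. No group was tested for a sample far from the others, because each group holds 3 libraries.

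A difference between groups drew attention to every value in this paragraph. The response to betulonic acid differed between AGS and HGC-27 for 8971 genes by edgeR's interaction test. In 100 drawn splits of the samples 1 result was as large, the real one, and the highest other was 5285. Every other split mixed treated and untreated libraries in at least 1 line, and the real split with HGC-27 reversed was not drawn. None kept the change in both lines while removing their difference, so the splits cannot decide on this count. Lists that differed by camera had median differences (AGS minus HGC-27, log2) of -1.82 for mitosis, 1.21 for the integrated stress response, -0.50 for the unfolded protein response, 0.93 for NRF2 targets, 1.02 for LXR targets, 0.55 for autophagy, 0.53 for glycolysis, 0.96 for nuclear oxidative phosphorylation genes, 1.20 for ribosomal proteins, -1.72 for DNA repair and 0.53 for the cytoskeleton. With an estimated correlation 0 lists differed, and the smallest adjusted p was 0.115. No scaling other than TMM was tried for these lists. With the length trend removed, mitosis and DNA repair passed with an estimated correlation (adjusted p = 0.0397 and 0.0323). Of 86 genes given a log2 change in the Results above 84 were tested in both lines and 71 differed, 35 above 0 and 36 below 0. Members of the gene families described further below are not among them. With limma on log2(FPKM + 1) 63 of the 71 had a value and 13 of these did not pass. These were DDIT3 (0.08), PPP1R15A (0.17), SYVN1, MCM2 (0.16), PARP1 (0.04), WIPI1, RPS12 (0.36), NDUFB5, SDHA (0.07), BST2, CDKN1A (0.18), FLNA (0.58) and MT-TY (0.24). With quantile normalization 10 of 71 did not pass. They were PPP1R15A (0.24), SYVN1 (0.08), MCM2 (0.27), PARP1, RPS12 (0.30), ATP5F1B (0.10), SDHA (0.15), CDKN1A (0.14), SPRR2D (-0.56) and FLNA (0.34). With median-ratio scaling TAGLN did not pass (-0.41).

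Among stress genes the differences were 0.80 for DDIT3, 6.98 for TRIB3, 0.67 for PPP1R15A, 3.22 for CHAC1, 1.51 for SLC3A2, -0.50 for XBP1, -1.02 for DNAJB9, 0.47 for SYVN1 (-0.11 on the FPKM scale), 10.62 for HSPA6 and 5.52 for DDIT4. NRF2, metal and autophagy genes gave 2.57 for HMOX1, 1.51 for SRXN1, -0.54 for OSGIN1, -1.14 for TRIM16, 5.41 for MT2A, 3.44 for MT1X, -1.95 for SLC30A1, 3.16 for SQSTM1, 0.52 for WIPI1 (-0.08 on the FPKM scale) and 1.35 for MAP1LC3B. For replication, mitosis and repair they were -2.18 for MCM10, -1.86 for CLSPN, -0.94 for TYMS, 0.73 for MCM2, -2.92 for MKI67, -3.84 for TOP2A, -3.06 for ECT2, -2.46 for KIF23, -3.11 for BUB1, -2.07 for FANCI, -2.28 for FANCD2 and 0.65 for PARP1 (-0.03 with quantile normalization). Lipid genes gave -1.70 for ACACA, -2.93 for HMGCS1, -2.26 for IDI1, -0.97 for INSIG1, 1.38 for SREBF1 and 2.67 for LPCAT3. Ribosome and mitochondrial genes gave 0.97 for RPS12, 1.40 for RPL3, -0.48 for MYC, -0.76 for NCL, -3.22 for UTP20, 1.79 for NDUFA1, 0.35 for NDUFB5 (-0.23 on the FPKM scale), 0.98 for ATP5F1B, 0.64 for SDHA and 0.81 for MT-TY. Immediate-early and p53-related genes gave 4.00 for EGR1, -2.26 for JUN, 3.51 for DUSP1, 4.87 for KLF2, 0.75 for CDKN1A, -1.80 for GDF15 and -0.86 for GADD45A. Interferon, matrix and cytoskeleton genes gave -1.80 for BST2 (0.14 on the FPKM scale), 4.50 for COL1A1, -3.54 for COL3A1, 3.95 for TGFB1, -1.81 for CALD1, -0.46 for TAGLN and 1.20 for FLNA. The others were -4.29 for SLC12A2, -4.59 for SPRR2D (3.21 on the FPKM scale), 5.09 for UPP1, -5.96 for ALPP, -1.88 for DKK1, -4.42 for ENC1, -5.43 for DHRS2, 2.39 for NES and -1.14 for H2AC6. The fitted differences of SPRR2D and COL3A1 rest on a group with near 0 counts and are no bound. That of ALPP sets AGS against HGC-27 libraries near 0 FPKM. COL3A1 in AGS was 101 times lower, with a counting interval of 13.7 to 3004 if its treated total of 3 counts is taken as 1 fragment.

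Genes with long transcripts fell and genes with short transcripts rose in AGS, with a Spearman rho of -0.31 across 12791 genes. At similar transcript length, genes spanning longer stretches of chromosome had changes lower by -0.41 than genes spanning shorter ones, against -0.08 to 0.09 in 1000 random divisions of the genes. Length was matched only within bins of relative transcript length, and random divisions do not keep a link of length and span inside a bin. A bias against long RNA in the treated libraries could thus give part of the AGS value, which cannot decide on that bias. The AGS value also goes with fewer transcripts from genes of long span. In HGC-27 the same value was 0.116, outside -0.06 to 0.08 in random divisions and opposite in direction. Whether the bias, a slowing of elongation or a loss of unstable transcripts underlies the AGS trend stays open.

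The mitochondrial mRNAs fell in both lines while the rRNAs MT-RNR1 and MT-RNR2 did not. Mean rRNA change minus median mRNA change was 3.34 in the line with the smaller gap. RN7SK, an RNA without a poly(A) tail, rose in both lines, and carry-over of RNA without tails was not tested. Such carry-over could hold up the rRNA values. The gap therefore cannot decide whether mitochondrial transcripts of every kind fell or other genes took up the counts. Transcripts ending early along the heavy strand would give larger falls farther from the promoter. Spearman's rho of change with position over 12 heavy-strand mRNAs was -0.35 in AGS (permutation p = 0.266), which leaves this undecided, as does -0.41 in HGC-27 (permutation p = 0.193). Poly(A) selection sees rRNA through short tails only, so a change in tails stays open.

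The mitosis list fell further in AGS than in HGC-27, by a median of -1.82 (camera adjusted p = 1.1e-12, and adjusted p = 0.115 with an estimated correlation). With the length trend removed the median difference was -1.85, so the trend does not account for it. Without treated AGS library 1, 2 or 3 it was -1.71, -1.78 and -1.85, with camera adjusted p of 4.4e-11 or smaller at the preset correlation. No single treated AGS library thus accounts for it, and the other libraries were not left out for this list difference. Each line had its own concentration, and the depth of growth arrest at 24 h was not measured here, so a difference in dose effect stays open.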

How the results depend on the processing

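The fits with counts divided by 4, without mitochondrial genes, on coding genes, with the length trend removed and on log2(FPKM + 1) were chosen only after the data were seen. Over all other settings the counts of called genes stayed within 1.5 times those reported, except as follows, and shared genes are not implied. With a log2 change of at least 1 required in addition, 6650 genes were called in AGS, 5223 in HGC-27, 5890 for the difference and 1583 in the same direction. With the stricter filter, which tests fewer genes, they were 4774, 5217, 3284 and 2365. With an estimated correlation 0 lists were called, against 41. Leaving out 1 library gave 8921 to 11201 genes in AGS, 10105 to 10535 in HGC-27, 8289 to 9601 for the difference, 3862 to 4676 in the same direction and 36 to 43 lists. The replicate block gave 9670, 10549, 8560 and 4193 genes and 43 lists, the AGS Wnt and fibroblast lists among them (adjusted p = 0.0323 and 0.0448), and called BCL2 (-0.49) but not ENC1 (0.375) in HGC-27. Same-numbered samples correlated at -0.051 to -0.018 in AGS and 0.001 to 0.017 in HGC-27, and 0 of 6 samples per line correlated best with their own number, so the numbers do not pair samples. Plain limma and the unfiltered fit apply to gene tests and were not run for lists. Across 70 list results, comparisons gave 953 same, 28 stronger, 95 weaker and 21 reversed, and across 188 gene results 2603 same, 9 stronger, 16 weaker and 13 reversed. The cause of the reversals was not tested.

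List medians on the log2 scale of camera, whose test direction reversed, were as follows. With the stricter filter they were -0.31 for AGS glycolysis, -0.0632 for AGS NF-kB, 0.0877 for AGS matrix genes, 0.15 for HGC-27 mitosis and 0.0368 for HGC-27 transporters. With quantile normalization they were -0.10 for AGS glycolysis, 0.0279 for AGS matrix genes, -0.18 for HGC-27 xenobiotic genes and -0.0052 for HGC-27 transporters. With fry they were -0.22 for AGS NF-kB, -0.20 for AGS matrix genes and -0.13 for HGC-27 xenobiotic genes. On log2(FPKM + 1) and log2(FPKM + 0.1) HGC-27 transporters had 0.25 and 0.30. Leaving out 1 library gave -0.31 to -0.0858 for AGS NF-kB, -0.51 to -0.16 for AGS matrix genes, -0.33 to -0.0383 for HGC-27 xenobiotic genes and -0.16 to -0.0012 for HGC-27 transporters. Genes that reversed were DDIT4 in HGC-27 (quantile 0.16, FPKM + 1 0.16, FPKM + 0.1 0.16, plain limma 0.16, leaving out 1 library -0.16 to 0.0487), UPP1 in HGC-27 (quantile -0.0162, leaving out 1 library -0.10 to 0.26) and HSPA7 in HGC-27 (quantile -0.38, leaving out 1 library -0.20 to 0.41). So did ALPP in HGC-27 (leaving out 1 library -1.42 to 0.26) and MYC in HGC-27 (quantile 0.0231). Library depth was 14.3 to 19.7 x 1e6 fragments, and its effect on genes with few counts was not tested.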

Other observations

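The gene families in the next paragraphs and the test on HNF4A were chosen only after the result was seen. Host genes of small nucleolar RNAs rose in 17 of 29 tested cases in AGS (median log2 change 1.31) and in 19 of 30 in HGC-27 (median 0.90). The growth-arrest transcript GAS5 rose by 3.45 ± 0.23 and 2.17 ± 0.08, and ZFAS1 by 3.30 ± 0.24 and 2.54 ± 0.09, while SNHG4 changed by -3.21 and -1.21 (SE, n = 3 libraries per group, edgeR). The median difference between lines was 0.39, and it turned to -0.17 on the FPKM scale. Genes of the ZNF family of zinc finger proteins went apart by line, with 189 of 404 lower and 96 higher in AGS (median -0.55) and 192 of 440 higher and 46 lower in HGC-27 (median 0.41). The interaction was called for 205 below and 55 above 0 of 385 genes, with a median of -0.98, or -0.66 with quantile normalization. With the length trend removed the AGS median was -0.30.

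Keratin genes fell in AGS in 17 of 23 cases (median -2.53) and rose in HGC-27 in 6 of 11, with 0 lower (median 1.72, or 1.41 with 2 genes at their bound). The interaction median over 10 genes was -3.35, or -2.99 with quantile normalization. Many keratins were scarce in HGC-27. KRT5, KRT16, KRT17, KRT75, KRT81 and KRT86 had 10 counts or fewer in each untreated library. On the FPKM scale only 1 keratin gene was tested for the interaction, and its difference of 0.33 was not called. KRT7 changed by -2.84 in AGS and 1.99 in HGC-27, while KRT16 rose by 6.96 in AGS and, from a count of 0, at least 8.02-fold in HGC-27. Cytosolic aminoacyl-tRNA synthetase genes rose in 13 of 20 cases and fell in 3 in HGC-27 (median 0.44) and in AGS rose in 8 and fell in 8 (median -0.22). WARS1 and SARS1 rose in both lines, by 2.27 and 1.95 in AGS and by 1.5 and 1.36 in HGC-27, and TARS1 changed by -0.60 in AGS and 1.05 in HGC-27. FTH1 pseudogenes rose in 10 of 11 cases in AGS and 5 of 8 in HGC-27, and they share reads with FTH1.

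HNF4A, a transcription factor of the gastrointestinal lineage, rose from a count of 0 in HGC-27 and is expressed in AGS. If AGS material had entered the treated HGC-27 libraries, other genes that AGS has and untreated HGC-27 lacks would have risen with it. Over 101 such genes the 90th percentile of the ratio of treated HGC-27 to treated AGS was 0.370%, 59 were at 0, and HNF4A was at 14.8%. The value argues against AGS material as the source.

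For the counts of called genes within 1 line, 10 splits of the 6 libraries cannot give a share under 0.05. In AGS 1 split was as large as the real 10311, the real one, and the highest other was 0. In HGC-27 1 split was as large as the real 10922, again the real one, and the highest other was 0. For genes changed in the same direction in both lines 1 of 100 drawn splits was as large as the real 4420, the real one, with 0 as the highest other. Every other split holds a wrong split of at least 1 line, which called 0 genes, so its shared count is fixed at 0 and the comparison cannot decide. For gene list tests 1 of 100 was as large as the real 41, the real one, but the highest other called 40 lists and their median was 28. At the preset correlation lists are thus called in many splits. The other splits hold unequal numbers of treated libraries in their groups, or keep the real split in 1 line. Their calls thus do not measure chance, and the comparison cannot decide. With an estimated correlation the real data called 0.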
